A study of Mus musculus with 12 samples.

How the data were processed

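Transcripts were measured by RNA sequencing in primary cells from the cerebral cortex of mouse fetuses. The cells were cultured with or without triiodothyronine (T3), the active thyroid hormone. Every library is titled wild type. The series holds 12 libraries, 6 from cultures without T3 and 6 from cultures with 10 nM T3 for 24 h. Each of 6 fetuses, numbered as mouse 1 to 6, gave 1 culture of each kind. Fetuses were taken on gestational day 17.5, the cells grew for 9 days, and the B27 supplement was withdrawn for 24 h before T3 was added. Libraries were made per the labels' protocols from 500 ng of total RNA with an Illumina TruSeq RNA kit of version 2. Single reads of 75 bases were produced on a Genome Analyzer IIx. This kit does not mark strand, so reads from a gene and from an overlapping gene on the other strand cannot be told apart.

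CASAVA, FastQC, Bowtie, TopHat, HTSeq, edgeR and the mouse build GRCm38 are named in the submitters' processing notes, and their versions are not given in the sources used here. The deposited values are a normalized signal: per the file headers, counts per gene scaled by TMM, a method that corrects library sizes for composition. The columns of the deposited signal sum to 969044 to 1044780, so a value is read here as TMM-normalized CPM, the reads of a gene scaled to the size of its library. The table of the whole series and the 12 files of single libraries held the same values, with a largest difference of 5.1e-11. The table lists 14801 genes, each at 1 CPM or more in at least 2 of the 12 libraries. A gene seen in 1 library alone would therefore not be listed.

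All values of a library were whole multiples of the value of 1 read, which gave back the reads behind them. With a tolerance of 0.01 reads, 100% of the values came out whole. The recovered totals ran from 5272092 to 10837895 reads per library, and 1 read was worth 0.0911 to 0.186 CPM. The limit that a count of 0 allows, taken as 3 reads, lay between 0.273 and 0.557 CPM and covers counting error only.

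The fixed plan assumed raw counts and named the quasi-likelihood test of edgeR, with the mouse as a block, as the main test. Because the deposited values are not raw counts, the main test was limma 3.58.1 in R 4.3.3 on log2(value + 0.5), with a mean-variance trend, robust estimation and the mouse as a block. The fold changes are on this scale, which understates the change of genes with low values. Genes were kept by the filterByExpr rule of edgeR 4.0.16 on the recovered reads, which left 13663 genes and removed 1138. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p given for a gene is from this limma fit unless another tool is named. The planned edgeR test was run on the recovered reads as an alternative, a choice made after the data were seen. It called 782 genes, 465 higher and 317 lower.

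The pairing comes from the series' design, which states that the cortices of a single fetus supplied both cultures. It was checked on the deviations of the libraries from their group means. The 6 pairs correlated between 0.237 and 0.638, each mouse's own partner was its best match, and the correlations between different mice had a median of -0.106 and a highest value of 0.348. No pair of libraries of a group agreed within sampling noise, since chi-square per degree of freedom over genes with at least 20 reads ran from 2.41 to 18.1.

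Before the data were examined, 45 gene lists with 858 genes were written from background knowledge. They cover cell type markers, pathways, receptors, metabolism and stress responses, and 44 of them had at least 5 tested members. The red blood cell list had none and was not tested. Lists were tested with camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 44 lists. The same test with an estimated correlation and the fry test were alternatives. Camera compares the members of a list with the other genes, while fry asks whether the members move one way on balance.

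The genes named in the text follow a rule written before the data were examined. Among genes past the threshold, with a mean log2 value of at least 1, the same direction in 6 of 6 mice and an established symbol, it takes the 12 largest increases, the 12 largest decreases and the 3 smallest p-values per direction. Thra, Thrb, Dio2, Dio3, Hr and Klf9 were named whatever their values. Any member of a fixed list may be named, and which members outside the 4 with the smallest p of a list are named was chosen after their values were seen. Gene symbols were found for 14648 of the 14801 identifiers. Overlaps with other genes over at least 10% of the exons of a named gene are given in the text. Coordinates and overlaps come from GENCODE release 21 for mouse on GRCm38, the build the submitters' notes name.

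The test was tried on simulated counts drawn from the means, dispersions and library sizes of these 12 libraries for 13663 genes, of which 200 were changed. A mouse effect of a size set by hand, not estimated, was the same in both cultures of a mouse. No simulated library was set apart from the rest, so recovery and false calls in the real data may differ. For the comparison of T3 with no T3, limma recovered 68.7% of genes changed 1.3-fold, 88.1% of those changed 1.5-fold and 93.9% of those changed 2-fold. It made 7 false calls, 4.02% of its calls. Of 200 random lists of 20 genes, drawn from all simulated genes with the changed ones among them, 9 had a camera p under 0.05. The genes were simulated independently of each other, so this does not show how camera behaves for lists of correlated genes.

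Alternatives set before the data were examined were a fit without the block, other scalings (RLE, upper quartile, library size), other filters, DESeq2 1.42.0 and limma-voom on the recovered reads, a stricter p, a test against a fold of 1.2, and leaving out each mouse. Added after the data were seen were pseudocounts of 0.1 and 1, reads thinned to the smallest library, and the lists without mouse 4 with an estimated correlation. The planned edgeR test was also moved to the recovered reads then, with and without the block. Exact tests flipped the sign of whole mice and were two-sided. Their smallest possible p with 6 mice is 0.03125.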

Results

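Primary cultures of cerebrocortical cells hold neurons and glia from the fetal cortex. The series compared 6 cultures given T3 with 6 cultures of the same 6 mice kept without it, to find which genes the hormone regulates in these cells. The libraries without T3 held 7008618 ± 951368 reads (SD, n = 6) and those with T3 9273960 ± 1421889 (SD, n = 6). The T3 library was the deeper one in 6 of 6 mice, by 1.03 to 1.67 times (exact sign-flip permutation test, p = 0.03125). Values are given below as TMM-normalized CPM, and each ± is the SD over 6 cultures.

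The library of mouse 4 without T3 stood apart from the others in a set of transcripts of heart and connective tissue. After 0.5 was added to each value, 52 genes in it lay over 4-fold above every one of the other 11 libraries, and no other library had such a gene. Myh7, a myosin heavy chain of heart muscle, stood at 705.8 CPM against at most 3.81 elsewhere. Ttn, the giant sarcomere protein, stood at 303.9 against at most 1.95. Col3a1, a collagen of connective tissue, stood at 110.6 against at most 6.74, and the imprinted RNA H19 at 485.4 against at most 2.73. Together the 52 genes took 0.363% of the reads of this library, which counts these genes alone. Of these genes 28 entered the test for an effect of T3, and 1 of them, Rbpms, passed it.

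**Figure D1:**
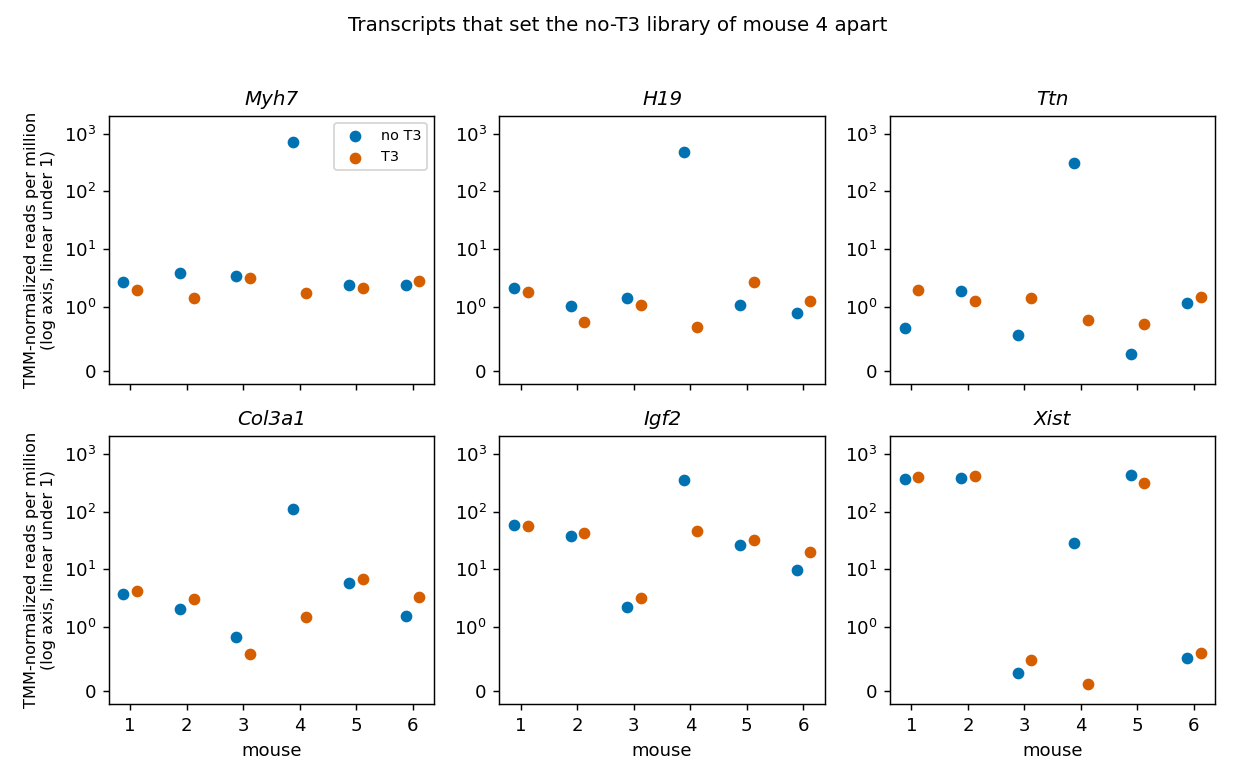
TMM-normalized CPM (vertical axis, logarithmic above 1) of 6 transcripts in each of the 12 libraries, by mouse (horizontal axis) and treatment (colour). The library of mouse 4 without T3 holds 705.8 for Myh7 and 485.4 for H19, while its Xist value of 28.02 lies between those of the other libraries.

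T3 changed a limited set of genes, most of them by small factors, and more of them rose than fell. The gene with the largest rise was Hr, a nuclear corepressor known as hairless, which went from 5.49 ± 1.24 to 46.5 ± 2.92 (n = 6), 7.99-fold. The morphogen gene Shh rose 4.60-fold and Dio3, the deiodinase that inactivates thyroid hormones, 3.46-fold. The guidance gene Sema3c rose 2.98-fold and the transcription factor gene Klf9 2.75-fold. The calcium-binding protein gene Calb1 fell from 42.7 ± 14.3 to 19.8 ± 3.39 (n = 6), and Rgs4, a brake on G protein signalling, from 197.9 ± 37.1 to 100.4 ± 15.6 (n = 6).

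Of the 13663 genes tested, 754 passed (5.52%), of which 461 were higher and 293 lower with T3. The median change was 1.3-fold among the genes that rose and 1.24-fold among those that fell. At least 2-fold, 18 genes rose and 2 fell, and at least 1.5-fold the counts were 101 and 32. The direction was the same in 6 of 6 mice for 389 of the higher and 261 of the lower genes. Leaving out 1 mouse gave 459 to 854 genes: 459 without mouse 3 (304 higher, 155 lower) and 570 without mouse 4 (340 higher, 230 lower), and without mouse 5 191 were lower. The same test without the mouse as a block called 178 genes, 125 higher and 53 lower, because the spread between mice then counted as error.

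Hr (ENSMUSG00000022096), on chromosome 14 from 70552212 to 70573548 of GRCm38, rose by 3.00 on the log2 scale (SE 0.095, adjusted p = 3.47e-14). Sema3c (ENSMUSG00000028780), on chromosome 5 from 17574281 to 17730268, rose by 1.57 (SE 0.061, adjusted p = 6.92e-13), and Kcnj10 (ENSMUSG00000044708), an inwardly rectifying potassium channel of glia on chromosome 1 from 172341210 to 172374085, by 1.31 (SE 0.059, adjusted p = 7.96e-12). Klf9 (ENSMUSG00000033863) lies on chromosome 19 from 23141226 to 23168134 and rose from 23.7 ± 4.71 to 65.4 ± 6.60 (adjusted p = 4.03e-11). Shh (ENSMUSG00000002633), on chromosome 5 from 28456815 to 28467256, rose from 1.85 ± 0.397 to 10.4 ± 2.29 (adjusted p = 1.19e-08). Annotated antisense transcripts cover 28.3% of the Shh exons, and their reads could not be separated from those of Shh. Dio3 (ENSMUSG00000075707), on chromosome 12 from 110279068 to 110281097, had low values, with 4 to 69 reads per library.

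The other large increases were of Flywch2 (2.92-fold), of the orexin receptor gene Hcrtr1 (2.63-fold), of Bcar3 (2.51-fold), of the small GTPase gene Rasd2 (2.45-fold), of the receptor tyrosine kinase gene Ret (2.43-fold) and of the septin gene Sept4 (2.37-fold). Adjusted p ranged from 3.36e-07 for Ret to 1.73e-05 for Bcar3, and all 6 of these genes were higher in 6 of 6 mice. An antisense transcript covers 12.5% of the Bcar3 exons. Bcar3 and Kcnj10 varied widely between mice, and their calls were lost when the mouse was not used as a block (adjusted p = 0.222 and 0.288).

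Among the genes that fell, Rgs4 (ENSMUSG00000038530), on chromosome 1 from 169741477 to 169747642, changed by -0.97 on the log2 scale (SE 0.050, adjusted p = 7.43e-11). Calb1 (ENSMUSG00000028222), on chromosome 4 from 15881264 to 15908064, changed by -1.052 (SE 0.089, adjusted p = 1.72e-07). Aldh1a3 (ENSMUSG00000015134), which makes retinoic acid and lies on chromosome 7 from 66390890 to 66427517, changed by -0.9957 (SE 0.083, adjusted p = 1.72e-07). Sfrp1 (ENSMUSG00000031548), a secreted Wnt antagonist on chromosome 8 from 23411502 to 23449632, fell from 296 ± 42.5 to 197.4 ± 29.2. The serotonin receptor genes Htr7 and Htr2a fell by 0.92 and 0.66 on the log2 scale, and the protocadherin gene Pcdh18 fell by 0.79. Ndst3, an enzyme of heparan sulfate synthesis, fell by 0.72, and Kera, a matrix proteoglycan, by 0.74. The calls of Kera and Htr2a were lost with DESeq2.

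Bub1 and Nuf2, which act at the kinetochore in mitosis, fell by 0.78 and 0.77 on the log2 scale, and Wdr76 fell by 0.64. These 3 genes had low values, with 16 to 51 reads per library. Rbpms, an RNA-binding protein gene, showed the largest decrease (log2 fold change -1.15, adjusted p = 0.0388), with 20.6 CPM in the no-T3 library of mouse 4 and at most 3.08 in the other 11 libraries. Without mouse 4 its log2 fold change was -0.80 (adjusted p = 0.0399). The call of Rbpms was lost without mouse 2 or 3, that of Bub1 without mouse 4, that of Wdr76 without mouse 4 or 5 and that of Htr2a without mouse 2, 3 or 6.

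**Figure D2:**
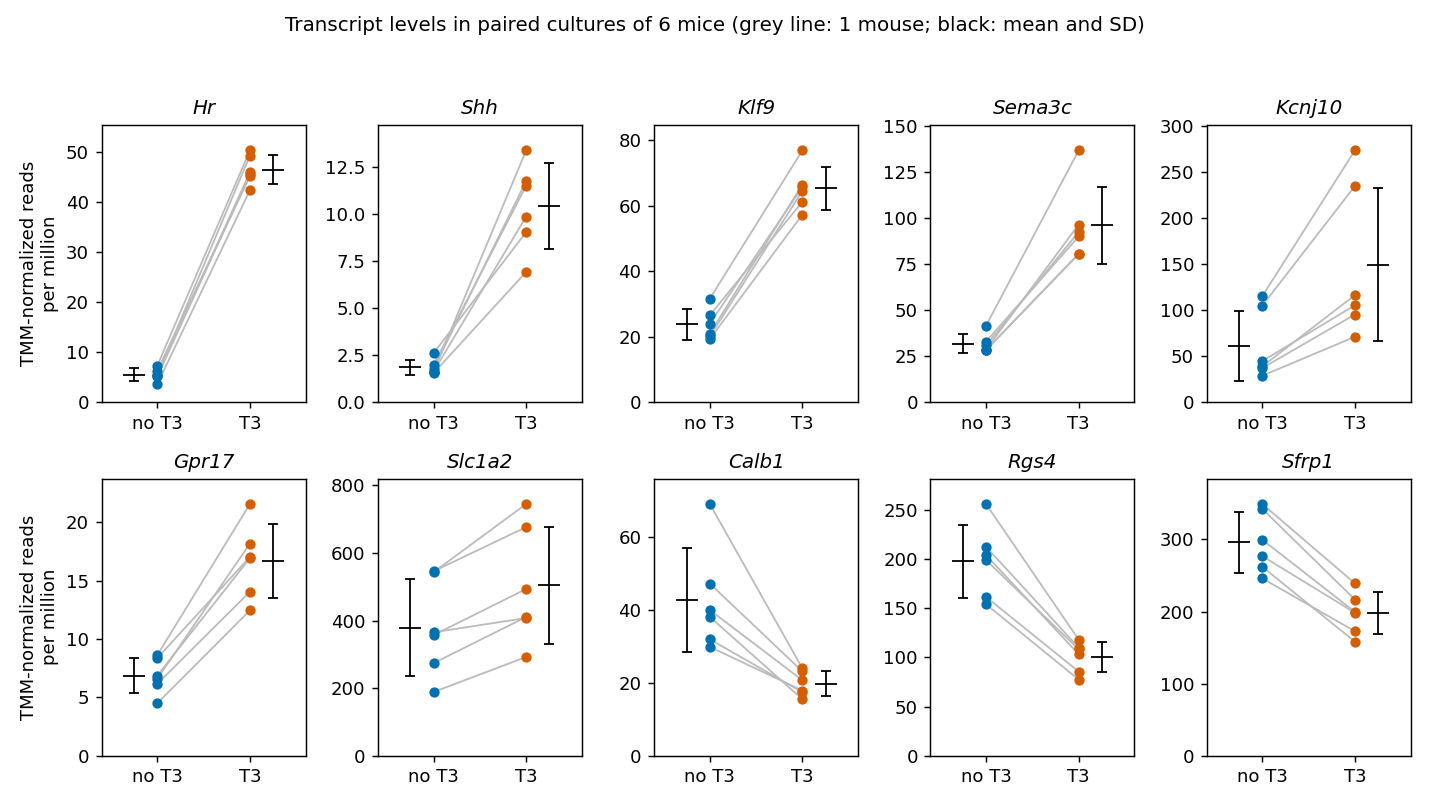
TMM-normalized CPM (vertical axes, linear from 0) of 10 genes in the 6 cultures without T3 (blue) and the 6 with T3 (orange). Each grey line joins the 2 cultures of 1 mouse, black marks give mean and SD, and the line of each mouse rises for the first 7 genes and falls for Calb1, Rgs4 and Sfrp1.

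Genes that earlier work had described as induced by T3 rose as a group. Of 31 tested members of that list, 19 rose and none fell (median log2 change 0.67). Besides the genes above they included Gls2, a mitochondrial glutaminase (1.22), Stac2 (1.053), Sema7a (0.92) and the clock output gene Dbp (0.83), with an antisense gene over 18.0% of the Dbp exons. The camera test gave an adjusted p of 3.41e-29, and 0.0179 with an estimated correlation. Adjusted over the list alone, 23 members rose and 1 fell. The list was written from general knowledge of T3 target genes and may hold genes first chosen on these samples, so it is not independent evidence of their direction. Of 11 members of the corresponding list of repressed genes, 2 fell, Aldh1a3 and the melanocortin receptor gene Mc4r (-0.61, call lost without mouse 1, 2, 3, 5 or 6). All 11 had a log2 change below 0 (camera adjusted p = 0.000218, and adjusted p = 0.151 with an estimated correlation). Adjusted over the list alone, 3 fell. The list of repressed genes was written in the same way as the induced one, so the same limit holds for it.

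The genes for thyroid hormone receptors did not pass the test. Thra stood at 1585 ± 110.8 without T3 and 1488 ± 146.4 with T3 (adjusted p = 0.353, n = 6), and Thrb at 42.4 ± 5.31 and 41.1 ± 3.47 (adjusted p = 0.832, n = 6). Nr1d1 lies antisense to 5.7% of the Thra exons. Dio2, the deiodinase that makes T3, was lower in 5 of 6 mice with a log2 change of -0.39 just short of the threshold (adjusted p = 0.0503), and it passed in 6 of 20 other settings: RLE scaling, a pseudocount of 1, DESeq2, limma-voom, edgeR with the block, and without mouse 6 (adjusted p from 0.00222 by limma-voom to 1 over the 20). Of the 20 tested genes for receptors, deiodinases, transporters and cofactors, 2 rose, Dio3 and the coactivator gene Ncoa1 (0.22), and 1 fell. This list did not pass the camera test (adjusted p = 0.377).

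Astrocyte markers were higher with T3. Of 20 tested, 8 rose and none fell, among them the glutamate transporter gene Slc1a2 (log2 change 0.43, from 379 ± 143.4 to 504 ± 173.8), the bicarbonate transporter gene Slc4a4 (0.44) and F3 (0.43). The list mean was above 0 in 6 of 6 mice, from 0.056 to 0.644. The camera adjusted p was 5.69e-10, and adjusted p = 0.471 with an estimated correlation. Of 13 markers of oligodendrocyte precursors 3 rose and 1 fell. Gpr17, a receptor of cells committed to the oligodendrocyte lineage, rose from 6.85 ± 1.52 to 16.7 ± 3.20 (log2 change 1.24, adjusted p = 1.22e-07). The lineage transcription factor genes Olig1 (0.41) and Olig2 (0.24) rose, and the matrix gene Vcan fell by 0.50. That list had a camera adjusted p of 0.0349, and adjusted p = 0.471 with an estimated correlation. Its call was lost without mouse 2, 4 or 6 (camera adjusted p = 0.07, 0.0867 and 0.0542). The call of Olig2 was lost without mouse 3, 4, 5 or 6. Of 8 tested markers of mature oligodendrocytes 1 rose, the galactolipid enzyme gene Ugt8a (0.62).

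Neuronal markers moved both ways. Among 18 excitatory markers 2 rose and 4 fell, with the vesicle protein gene Sv2b at -0.34. Among 19 inhibitory markers 3 rose and 3 fell, with the calcium-binding protein genes Calb2 at 0.45 and Calb1 at -1.052. Among 20 pan-neuronal markers 3 rose and none fell. These lists had camera adjusted p of 0.504, 0.998 and 0.978. No member passed in the lists of microglia (5 tested), endothelium (6 tested) and choroid plexus and ependyma (6 tested), with adjusted p of 0.998, 0.587 and 0.458. The mean of the endothelial list was -1.33 in mouse 4 and between -0.268 and 0.425 in the others.

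Cell cycle genes were lower with T3. Of 30 tested, 5 fell and none rose: Bub1 and the genes Mcm2, Mcm3, Mcm5 and Mcm6 of the replicative helicase, with log2 changes from -0.35 to -0.78. The camera adjusted p was 5.46e-10, and adjusted p = 0.471 with an estimated correlation. The list mean was below 0 in 6 of 6 mice, with -1.01 in mouse 4, whose no-T3 library held the heart and connective tissue transcripts, and -0.086 to -0.318 in the others. Without mouse 4, 2 of these 5 passed, Mcm2 and Mcm6, and the camera adjusted p was 4.54e-06 (0.215 with an estimated correlation). Mki67, which had not passed with all 6 mice, also passed without mouse 4 (-0.53, adjusted p = 0.0181). The call of Mcm6 held without any one mouse, that of Mcm2 was lost without mouse 1, 2 or 3, that of Mcm5 without mouse 3, 4 or 6 and that of Mcm3 without mouse 1, 3, 4, 5 or 6. Among 16 markers of neural progenitors 1 rose, Prom1 (0.29, call lost without mouse 1, 2, 3, 4 or 6). That list had a camera adjusted p of 0.0306, and adjusted p = 0.694 with an estimated correlation. Its call was lost without mouse 1, 4 or 6 (camera adjusted p = 0.109, 0.0867 and 0.248).

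Markers of mural cells and meningeal fibroblasts followed the library of mouse 4. Of 12 tested, 1 fell, the proteoglycan gene Dcn (-0.47, call lost without mouse 3), with a camera adjusted p of 0.00515 and adjusted p = 0.725 with an estimated correlation. The list mean was -2.02 in mouse 4 and between -0.373 and 0.343 in the other mice, and without mouse 4 the median log2 change went from -0.50 to 0.01 (adjusted p = 0.643). Of 34 extracellular matrix genes 3 rose and 2 fell (adjusted p = 0.341), with a list mean of -0.81 in mouse 4.

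**Figure D3:**
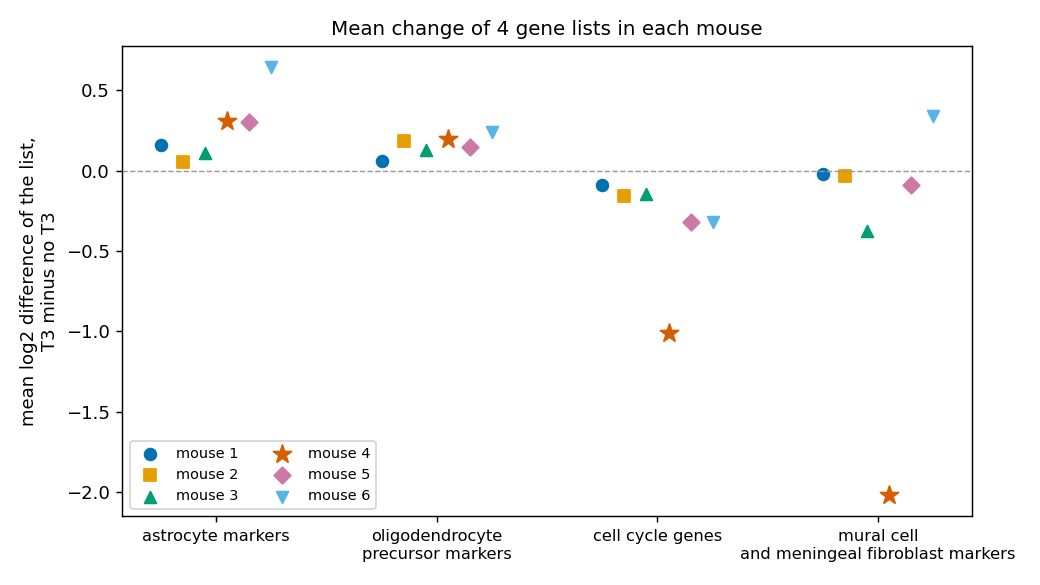
Mean log2 difference between the T3 and the no-T3 culture (vertical axis) of 4 gene lists (horizontal axis), 1 symbol per mouse. Mouse 4 (star) lies at -1.01 for cell cycle genes and -2.02 for mural and fibroblast markers, away from the other 5 mice.

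Genes of developmental signalling changed member by member. Of 11 Hedgehog pathway genes 3 rose and none fell, the ligand gene Shh, its receptor gene Ptch1 (log2 change 0.47) and the coreceptor gene Gas1 (0.42), which an antisense transcript overlaps over 19.9% of its exons. The camera adjusted p was 0.000472, and adjusted p = 0.359 with an estimated correlation. Of 10 retinoic acid genes Cyp26b1, which degrades retinoic acid, rose from 7.28 ± 2.40 to 16.1 ± 4.27 (log2 change 1.12), Aldh1a1 rose (0.70, call lost without mouse 1, 3, 4, 5 or 6) and Aldh1a3 fell. Of 16 Notch genes 2 rose, Hey1 (0.35) and Nrarp (0.84), and an antisense transcript covers 79.4% of the Nrarp exons. Of 16 Wnt genes Dkk3 rose (0.33) and Sfrp1 fell, and of 19 BMP and TGF-beta genes 1 rose. These lists had camera adjusted p of 0.998, 0.121, 0.998 and 0.377.

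Axon guidance genes also went both ways. Of 28 semaphorins and receptors 6 rose and 3 fell. Sema3c, Sema6c (log2 change 0.79), Sema7a (0.92) and the receptor gene Plxnd1 (0.54) were among those that rose, and the receptor genes Plxnc1 (-0.52) and Nrp1 (-0.36) among those that fell. Of 32 genes for ephrins, netrins, slits and their receptors 6 rose and 6 fell, with Epha4 (0.56) and Ephb1 (0.66) among the first and Unc5d (-0.48) and Efnb2 (-0.38) among the second. The adjusted p of the lists was 0.542 and 0.888, in tests of a common direction, which do not measure changes that go both ways. Among all genes tested 5.52% passed, and no test compared the share in these lists with that.

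Receptor genes for the transmitter GABA were lower on balance. Of 12 tested genes for GABA-A receptor subunits 3 fell, Gabra2 (log2 change -0.44), Gabra5 (-0.31) and Gabrg1 (-0.23, call lost without any one of mouse 2 to 6), and Gabrg3 rose (0.27, call lost without mouse 1 or 4). The list mean was below 0 in 6 of 6 mice (camera adjusted p = 0.000472, and adjusted p = 0.521 with an estimated correlation). Adjusted over the list alone, 9 members fell and 2 rose. Of 15 ionotropic glutamate receptor genes 1 rose and 2 fell, with Grin3a at -0.48. Of 26 potassium channel genes 2 rose and 1 fell, of 20 sodium and calcium channel genes 2 rose, Cacna1a (0.38) among them, and 2 fell, and of 24 synaptic vesicle genes 2 fell. The camera adjusted p of these lists was 0.62, 0.62, 0.523 and 0.888.

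Of 23 neuropeptide and growth factor genes 5 rose and 4 fell (camera adjusted p = 0.777). Igf1, a growth factor, rose from 28.3 ± 3.77 to 48.9 ± 4.31 (log2 change 0.79, adjusted p = 1.72e-07), the secretogranin gene Scg2 rose (0.49) and so did the nociceptin precursor gene Pnoc (0.68). Of 18 clock genes 4 rose and 1 fell (adjusted p = 0.121), with Hlf at 0.62 and Nr1d1 at 0.36, a gene that overlaps Thra over 8.5% of its exons. Of 19 immediate early genes 2 fell, Fosl2 (-0.51) and Nr4a3 (-0.32), and none rose (adjusted p = 0.977). Of 16 genes of p53 and apoptosis 1 rose, the pro-apoptotic gene Bcl2l11 (0.65), and 1 fell, with adjusted p = 0.341 for the list.

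Few metabolic genes passed the gene test. Of 15 genes of fatty acid synthesis 4 rose, Gpam (log2 change 0.30), Elovl5 (0.27), Me1 (0.21, call lost without mouse 2 or 4) and Acss2 (0.34, call lost without mouse 3, 4 or 5). Of 19 glycolysis genes 2 rose, Pfkfb3 (0.29) and Pgk1 (0.27, call lost without any one of mouse 1 to 5). Of 32 nuclear genes of the respiratory chain 31 had a log2 change above 0 and 3 rose, Ndufa5 (0.29), Cox5a (0.21) and Ndufa1 (0.27), with the call of Ndufa5 lost without mouse 6, that of Cox5a without mouse 2, 3, 4 or 6 and that of Ndufa1 without mouse 2, 4, 5 or 6. An antisense transcript covers 12.8% of the Cox5a exons. None of 23 cholesterol synthesis genes passed, and 20 had a value below 0, but the list mean was -0.535 in mouse 6 and -0.162 to 0.236 in the others, and without mouse 6 it went from -0.105 to -0.0187 (adjusted p = 0.581). The camera adjusted p of these 4 lists was 0.00427, 0.00515, 1.02e-05 and 0.00515. With an estimated correlation it was adjusted p = 0.471, 0.689, 0.471 and 0.812. No mitochondrially encoded gene (7 tested) and no cytosolic ribosomal protein gene (32 tested) passed, with camera adjusted p of 0.888 and 0.339.

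Stress response genes rose in small numbers. Of 16 genes of the NRF2 oxidative stress response 3 rose, Gstm1 (0.25), Cat (0.19) and Srxn1 (0.19), and all 16 had a log2 change above 0. Of 11 heat shock genes 2 rose, Hsph1 (0.19) and Hspa1a (0.28), a gene whose near-identical copy Hspa1b could share its reads. An antisense transcript covers 19% of the Hspa1a exons. The call of Srxn1 was lost without any one mouse, that of Hspa1a without any one of mouse 2 to 6, that of Gstm1 without any one of mouse 3 to 6, that of Cat without mouse 3, 4 or 6 and that of Hsph1 without mouse 2, 3 or 4. None of 17 genes of the amino acid response passed. Without mouse 6 the mean of that list went from 0.0925 to 0.0497 (adjusted p = 0.222) and that of the NRF2 list from 0.121 to 0.0778 (adjusted p = 0.00904). The camera adjusted p of these 3 lists was 0.000596, 0.0164 and 0.0293. With an estimated correlation it was adjusted p = 0.488, 0.359 and 0.694. Of 8 interferon response genes 1 rose and of 11 genes of neuroinflammation 1 rose, while none of 16 genes of the unfolded protein response passed, with camera adjusted p of 0.377, 0.557 and 0.542.

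**Figure D4:**
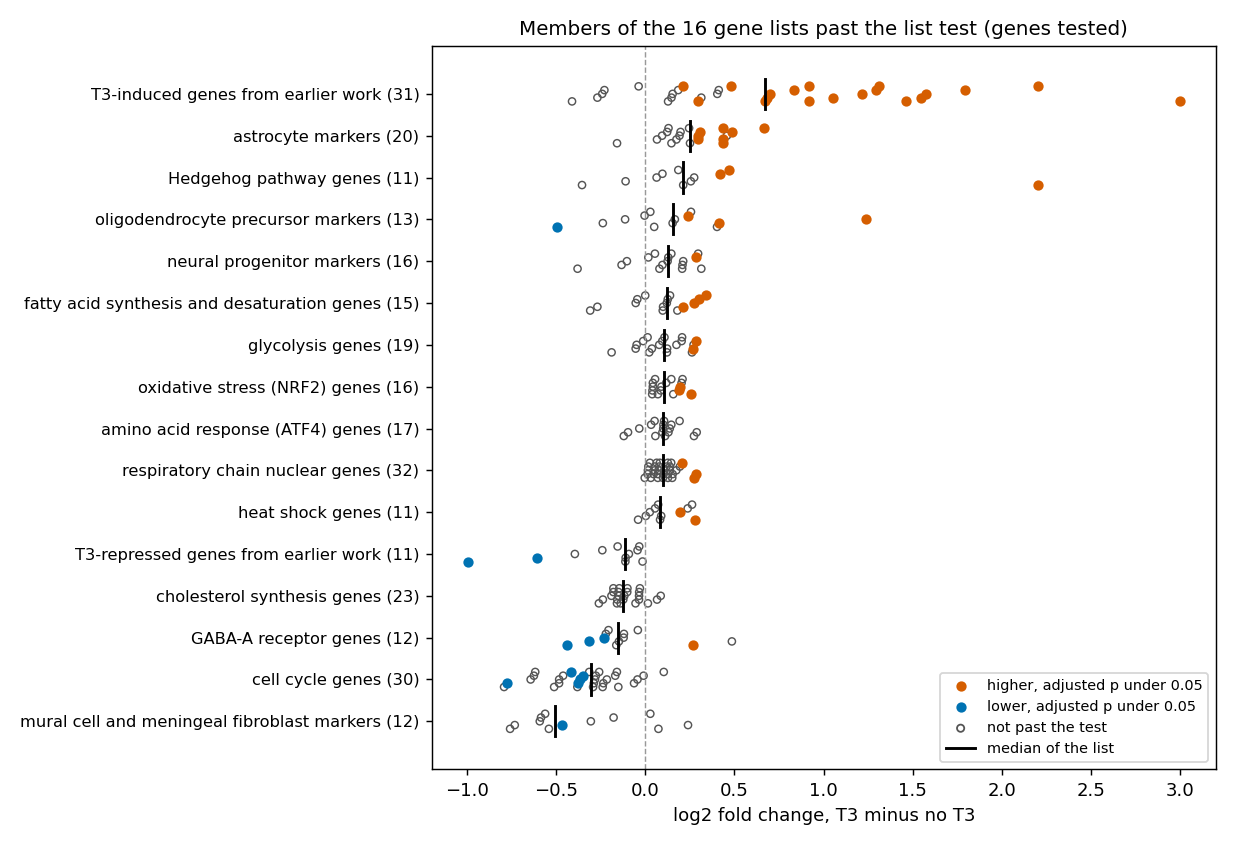
Log2 fold change with T3 (horizontal axis) of each member of the 16 lists past the camera test with a preset correlation, with filled points for genes past the gene test and a bar at each median. The T3-induced list has a median of 0.67, and the medians of the other lists lie between -0.50 and 0.25.

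In all, 16 of the 44 lists passed with the preset correlation, 11 of them higher and 5 lower, and 1 of them, the T3-induced genes, passed with an estimated correlation. In 7 lists, none of them past the test, the median, the mean and the test differed in sign: inhibitory neuron, pan-neuronal and microglial markers, and immediate early, Wnt, ionotropic glutamate receptor and interferon genes. When the 2 cultures of mice were exchanged, 5 of the 32 arrangements, the real one included, gave at least 16 lists, while none but the real one gave more than 3 genes.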

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

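The tests on the no-T3 library of mouse 4 and on the cell cycle genes were chosen after those results were seen. Each named gene, each list and the depth were checked for 1 library far from the other 5 of its group, by the gap to the nearest library divided by the range of the group. Of 282 such groups 17 passed Dixon's 95% limit, where chance alone gives about 14.1, and 2 of the 17 concern the no-T3 library of mouse 4. A further 5 genes, Myh7, H19, Ttn, Myh6 and Col3a1, were picked because this library stood out in them, so that they passed too says nothing about chance.

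In the no-T3 library of mouse 4 the gap took 0.93 of the range for Myh7, 0.891 for H19, 0.81 for Ttn, 0.832 for Myh6, 0.65 for Col3a1, 0.898 for Rbpms and 0.738 for the mean of the cell cycle genes. Xist stood at 28.02 CPM (151 reads) in this library although it held reads of Y-linked genes. The other 5 libraries with such reads had at most 0.593, and the 6 libraries without them 315.6 to 420.6, so that this value is 7.35% of the mean of those 6. Marker lists of 5 tissues were written after the library was seen and before they were tested, and folds are of values with 0.5 added. Of 13 listed genes of heart muscle all 13 lay above the other 11 libraries and 9 over 4-fold above them, with Myh7 at 705.8 as the most abundant, none in the lists fixed earlier and 1 with a median of at least 10 CPM in the other libraries. Of 17 listed genes of fibroblasts and vessel walls 16 lay above the others and 9 over 4-fold above them, with H19 at 485.4 as the most abundant, 11 in the lists fixed earlier and 5 with a median of at least 10 CPM elsewhere. No listed gene of skeletal muscle (4, the most abundant Acta1 at 9.46), liver (1, Ttr at 138) or epithelium (2, the most abundant Krt18 at 1.299) lay over 4-fold above the others, and Acta1 alone lay above them all. The lists as written held 34 genes for heart muscle, 18 for fibroblasts and vessel walls, 20 for skeletal muscle, 13 for liver and 11 for epithelium. A gene seen in 1 library alone is not listed, and Ttr had a median of 160.8 CPM in the other libraries. Skeletal muscle, liver and epithelium can therefore not be called absent from this library.

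A library of cells without neurons under this label is argued against by 20 pan-neuronal markers, whose median log2 difference from the other libraries was -0.0856. All libraries come from cortical cultures, so these markers cannot show an exchange with another culture of the series. For an effect of culture without T3, the biological explanation that the design gives, the 52 genes were looked at in the other 5 mice. Their median log2 difference was 0.0513 there, against -3.47 in mouse 4. These genes were chosen for lying above all other libraries, the other no-T3 cultures included, which largely fixed that contrast. The values show that the other no-T3 cultures lacked these levels, and they do not test such an effect. RNA of another animal with Xist, from heart and connective tissue, was proposed from these values and stays a hypothesis. If that RNA held Xist at the mean level of the libraries without Y-linked reads, its share would change 4 Y-linked genes by -0.11 on the log2 scale. That level was assumed and not tested. These genes differed by -0.0478 from the other 5 libraries that hold them, where the SD of 0.121 is too wide to decide. Whether such RNA came with the dissected tissue or entered later was not tested. The lists of mural cells, endothelium and matrix had their lowest means in mouse 4.

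Cell cycle genes were lower with T3, by a mean of -0.34 ± 0.34 on the log2 scale (SD, n = 6, below 0 in 6 of 6 mice, exact p = 0.03125, adjusted p = 0.115 over 44 lists). RNA of another tissue in mouse 4 as the whole cause is argued against by the other 5 mice, 5 of 5 below 0, with a mean of -0.205 ± 0.107 (SD, n = 5, exact p = 0.0625, the smallest that 5 mice allow). With reads thinned to the same number the mean was -0.363 ± 0.34 (SD, n = 6) and ranged from -1.02 to -0.113. This argues against counting noise and the added 0.5 in the shallower libraries as the cause. Thinning leaves the expected CPM of a gene unchanged, so it cannot test other differences between libraries that go with depth. How much of the -1.01 of mouse 4 came from another tissue stays open. An effect of T3 may remain as a hypothesis, and with an estimated correlation the list did not pass (camera adjusted p = 0.471, and 0.215 without mouse 4).

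The remaining single libraries far from their group are given with the share of the range in the gap. Without T3, Prom1 was high in mouse 1 (0.843, 48.3 against at most 23.6) and Cox5a low there (0.752). Gabrg1 (0.696), Dbp (0.664) and Sv2b (0.772) were low in mouse 6 without T3. With T3, Sv2b (0.821) and Hcrtr1 (0.627) were low in mouse 6, and Sema3c (0.657, 136.8 against at most 96.5) and Mc4r (0.642) were high there. Cat was high in mouse 1 (0.774) and Grin3a in mouse 5 (0.634), both with T3. Among list means with T3, mouse 1 was low for excitatory neuron markers (0.761), pan-neuronal markers (0.627) and synaptic vesicle genes (0.748), and mouse 5 was high for ionotropic glutamate receptors (0.658).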

How the results depend on the processing

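The pseudocounts, the thinned reads and the lists without mouse 4 with an estimated correlation were added after the data were seen. Apart from edgeR, the other settings were planned. The edgeR fit with the block was the planned main test. Its use on the recovered reads, with and without the block, was decided after the data were seen. None of the 754 genes took the opposite sign in any setting run on genes. Their number was between 531 and 798 with other scalings, filters and pseudocounts, edgeR with the block, DESeq2, limma-voom and thinned reads. The number of lists, 16 in the report, was between 14 and 16 with RLE and library size scaling, filters, pseudocounts and thinned reads.

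Without the replicate block 178 genes passed, 125 higher and 53 lower, and 11 lists. With edgeR on the recovered reads without the block 182 passed, 125 higher and 57 lower. In both fits differences between mice enter the error. With an adjusted p under 0.01 the counts were 392, 256 and 136, and against a fold of 1.2 they were 70, 58 and 12, both being stricter thresholds. The number of lists past the test was 1 with an estimated correlation between genes, 5 with fry (4 of the 16 and the Notch list), and 1 without mouse 4 with an estimated correlation, and the cause was not tested.

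Leaving out 1 mouse gave 459 to 854 genes, 304 to 526 higher and 155 to 328 lower, and 12 to 15 lists, with fewer samples in each fit. Without mouse 3 the counts were 459, 304 and 155, of which 298 higher and 153 lower genes are among the 754, and without mouse 5 191 were lower. The lists of neural progenitors (without mouse 1, 4 or 6), oligodendrocyte precursors (2, 4 or 6), the amino acid response (3 or 6), glycolysis (5 or 6), heat shock (2), mural cells (4) and cholesterol synthesis (6) lost their calls, and without mouse 6 the matrix list passed (adjusted p = 0.0121). Of 94 called genes followed by name, 29 passed in each of the 20 settings. Among the genes the report names, the calls of Srxn1, Mcm3, Gabrg1 and Rbpms were lost under at least 1 other scaling. Of the genes followed by name 18 lost their call with DESeq2. Srxn1, Mcm3, Gabrg1, Kera, Htr2a, Wdr76, Mc4r, Mcm2, Mcm5, Olig2, Prom1 and Cox5a were among them. With thinned reads 8 lost their call: Srxn1, Mcm3, Gabrg1, Aldh1a1, Acss2, Mc4r, Mcm5 and Ndufa1. The planned run of limma on the TMM table became the test reported here and was not run separately. The planned stricter filter left 14070 genes, more than the 13663 of the filter used.

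In simulated data at the depth of these libraries limma recovered 68.7% of genes changed 1.3-fold in the comparison of T3 with no T3, and 93.9% of those changed 2-fold. With reads thinned to 5272092 per library 677 genes passed, of which 384 higher and 227 lower ones are among the 754. Of the 123 called genes with a mean below 10 CPM 38.2% were lost on thinning, against 15.2% of the 631 at 10 CPM or more, a split by level made after the other results were seen.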

Other observations

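The counts over other arrangements of the libraries were planned, except the exchange within mice without blocks, while that count, the tests on the astrocyte markers and the look at differences between mice were chosen after the results were seen. With the 2 cultures exchanged within mice, 1 of 32 arrangements, the real one, gave 754 genes or more. The highest of the others gave 3. The share of 0.03125 is the smallest that 6 mice allow, so it argues against chance for the number of genes but cannot exclude it. For lists past the camera test, 5 of 32 arrangements gave 16 or more, the real one included, and the highest of the others gave 19, so chance is not excluded for the number of lists. The estimated correlation lay above the preset 0.01 in 39 of 44 lists. Without blocks, 1 of 100 arrangements of the 12 libraries, the real one, gave 178 genes or more, and the highest of the others gave 6. Most of these put both cultures of some mice on 1 side, unlike the real one. Over the 32 arrangements that part the cultures of each mouse, 1, the real one, gave 178 or more without blocks. The highest of the others gave 0, which argues against chance for this count with the same limit.

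Astrocyte markers were higher with T3, by a mean of 0.26 ± 0.21 on the log2 scale (SD, n = 6, above 0 in 6 of 6 mice, exact p = 0.03125, adjusted p = 0.115 over 44 lists). Deeper T3 libraries are argued against by thinned reads, where the mean was 0.269 ± 0.193 (SD, n = 6) and ranged from 0.099 to 0.618. A lower share of neurons that raises all other cell types alike stays open, since without mouse 4 the astrocyte list exceeded the mean of the microglial, mural and endothelial lists, each with the same weight, by 0.207 ± 0.21 (SD, n = 5) and in 3 of 5 mice. Both this weighting and a pooling of the 23 genes, 12 of them mural, were computed, and the pooled difference was 0.23 ± 0.191 (SD, n = 5), above 0 in 5 of 5 mice, while the lists taken singly gave 3 of 5 mice for microglia, 4 of 5 for endothelium and 5 of 5 for mural cells. More astrocytes and more transcripts per astrocyte cannot be told apart: the 20 markers ranged from -0.158 to 0.665, wider than their errors (Cochran Q 89.7 on 19 degrees of freedom, taken as independent), which goes against a common factor, but markers also expressed by other cells would spread too, and a share of 0.0625 of the 64 sign flips of the mice spread them as widely (smallest possible 0.03125).

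The first principal component of the log2 values held 31% of the variance and placed the libraries of mouse 1 at its low end (-25.6 and -33.5) and those of mouse 6 at its high end (31.6 and 17.9). The second held 16% and set the no-T3 library of mouse 4 apart (-39.1).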
